A study of Mus musculus with 8 samples.

How the data were processed

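The study measured mRNA in Min6 cells, a mouse insulinoma line with properties of pancreatic beta cells, after transfection with a plasmid that expresses Zac1 or with a control plasmid that expresses a nuclear-localised green fluorescent protein. Zac1 is the zinc finger transcription factor encoded by the imprinted gene Plagl1. Each group held 4 libraries, numbered 1, 2, 3 and 5 in both groups, and the series' design text calls them biological replicates. RNA was prepared 16 h after lipid-mediated transfection and made into stranded mRNA libraries, per the labels' protocols.

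The authors deposited 1 table of raw counts, whole numbers of reads per gene for 23100 genes in 8 libraries. The reads were processed with bcl2fastq 2.17, FastQC, TopHat2 2.1.1, Bowtie2 2.2.8 and HTSeq 0.6.1p1 on the mouse build mm9, per the submitters' processing notes. The gene annotation, the strand setting of the counting and any filter are not given in the sources used here. Gene counting of this kind cannot part reads of the transfected Plagl1 coding sequence from those of the endogenous gene, and overlapping genes on opposite strands are reported as uncertain. The transcripts of the mitochondrial genome were not analysed here, since none of the 13 list members had a matching symbol. No entry of the table lacked a gene name, and every one of the 8 columns matched 1 sample title.

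Library totals ran from 30.5 to 42.4 M (mega) counts. At the shallowest library, 3 counts correspond to 0.0982 CPM (counts per M counts of the library), and this floor of 3 counts, taken over the group, was used where a group had 0 counts. Counting intervals (95%) cover counting error only, since reads without molecular identifiers are not independent molecules.

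Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 14331, library sizes were scaled by TMM, and the quasi-likelihood fit and F test were run with robust estimation on a model with an intercept and the group. The Benjamini-Hochberg adjusted p threshold was 0.05, and a called gene is one past it. A log2 fold change is Zac1 minus control, its standard error (SE) was derived from the fold change and its F statistic, and levels are CPM with TMM-scaled totals, given as mean ± SD over the 4 libraries of a group. Where the controls had only a few counts, this SE can be smaller than the counting error, and the fold is imprecise. The level of Plagl1 was also compared by a two-sided exact permutation test of log2 CPM over the 70 assignments of libraries to groups. The steps were tested on simulated counts for the same comparison, with changed genes drawn at known folds among 14331 genes. edgeR recovered 82.4% of the 1.5-fold higher and 75.8% of the 1.5-fold lower genes, 94.1% and 78.8% at 2-fold, and 100% and 97% at 4-fold, with 15 false calls among 191. With the replicate number as a block it made 24 false calls among 198. The changed genes were drawn regardless of level above a low mean count, and the simulated libraries were not paired. The rates therefore do not give the recovery at the low levels where most called genes lay.

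For the gene lists, 50 lists were written before the data were examined, and 47 had at least 5 tested members. Each was compared with the other genes by camera in limma 3.58.1, on voom log2 CPM with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 47 lists. Camera with the correlation estimated per list, and the self-contained test fry, were alternatives. The lists of matrix genes were drawn up knowing that the study's paper names extracellular matrix genes, and those of network members and reported targets rest on published work by the same field, so none of these is independent of the study. The share of imprinted genes called was compared with that of all other tested genes other than Plagl1 by a two-sided Fisher's exact test. The same test was run on each of the 47 lists, and its p was adjusted by Benjamini-Hochberg over them. List members near silence in both groups were removed by the filter, while those that rose from near silence were kept. The share called and the shift of a list with many silent members are therefore raised by the filter.

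The genes named follow a rule fixed before the data were examined: Plagl1; the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 50 counts and non-overlapping groups, unnamed gene models passed over; for each list the 4 members with the smallest p and each called member where at most 10 were called; and each tested member of the imprinted gene network and reported target lists, with the paralogs Plag1 and Plagl2. For the second part, 119 genes were eligible among the increases and 0 among the decreases. A few genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

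The shared replicate numbers were examined before the fits were compared. Deviations of log2 CPM from the group mean, over the 11379 genes with a mean above 100 counts, correlated across genes at 0.54, 0.1035, 0.36 and 0.59 between the same-numbered libraries 1, 2, 3 and 5. Each exceeded the threshold of 0.1, number 2 only barely, and control library 2 correlated best with Zac1 library 3. Over all 14331 tested genes the correlations were 0.29, 0.05, 0.14 and 0.29. The numbers were therefore taken to pair the libraries on the more deeply counted genes, and values from a fit with the replicate number as a block are given where they change a call or move a count by over 1.5 times. The labels do not state what a number marks.

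Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, a test against a 1.2-fold change, RLE, upper-quartile and library-total scaling, no filter on low counts, a filter at a mean of 50 counts, the replicate block, Plagl1 left out of the scaling, and each library left out in turn. Alternatives added after seeing the data were both libraries numbered 5 left out, counts thinned to the smallest total, a correction for a GC content trend per library, and the block with either of the last 2. GC content, length and gene order came from a GRCm38 annotation, which is not the build of the counts. It was used without coordinates, and GC content was known for 13660 tested genes (95.3%). Of the 23100 gene identifiers, 22982 were found in the reference table. Figures were drawn with matplotlib 3.10.9.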

Results

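Counts per gene were available for 8 libraries of Min6 cells 16 h after transfection, 4 with the Zac1 plasmid and 4 with the control plasmid. The control libraries held 34.7, 35, 32.4 and 30.5 M counts (replicates 1, 2, 3 and 5), and the Zac1 libraries 41.6, 34.7, 41.2 and 42.4 M. Between 17382 and 17989 genes had at least 1 count in a library. The insulin genes Ins1 and Ins2, outside the naming rule and chosen after their values were seen, together took 3.82% to 5.47% of the counts in the control libraries and 4.33% to 4.97% in the Zac1 libraries. Replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom of 10.27 to 35.27, so none was a copy of another. The comparison is with counting noise only, so it cannot tell separate cultures from repeat preparations of 1 culture. All levels below are CPM over n = 4 libraries per group.

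The transfected gene itself was examined first. Plagl1 stood at 4631 ± 778 CPM in the Zac1 libraries and 77.8 ± 7.38 CPM in the control libraries, a 59.6-fold difference (log2 5.90 ± 0.13, SE; edgeR adjusted p = 1.45e-09). Its reads made up 0.466% of counts in the Zac1 libraries and 0.0077% in the controls, on average. The 2-group permutation test gave an exact p = 0.0286, which is the smallest that the 70 assignments allow. These assignments do not keep the pairing by replicate number. Plasmid-derived and endogenous transcripts are counted together in this value. The paralogs did not pass the test: Plagl2 differed by a log2 of 0.12 ± 0.06 (edgeR adjusted p = 0.734) and Plag1 by 0.04 ± 0.25 (edgeR adjusted p = 0.99).

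The series asked which genes respond to Zac1. Of 14331 tested genes, 313 were called, of which 308 were higher and 5 lower in the Zac1 libraries. Plagl1 is among the 308. At least 2-fold increases were found for 233 genes and at least 4-fold increases for 110. The largest increase under the naming rule was that of Mag, the myelin-associated glycoprotein, at 3.90 ± 0.296 CPM against 0.0305 ± 0.00197 CPM (115-fold, log2 6.85 ± 0.26, edgeR adjusted p = 1.45e-09). Mag had 1 count in each control library, so its control SD and SE understate the counting error of this fold. It was followed by Col9a2, a chain of the fibril-associated collagen IX, at 40.4-fold, and by Flnc, the actin cross-linking filamin C, which rose from 0.711 ± 0.166 to 9.23 ± 1.92 CPM (12.9-fold). Pgf, a growth factor of the VEGF family, rose 7.0-fold, and Hr, a nuclear receptor corepressor, 6.80-fold. Col2a1 rose 6.22-fold, the transmembrane protein Crim1 5.18-fold and the septin Sept4 4.25-fold. Ptprv, a receptor-type tyrosine phosphatase, was 6.26-fold higher, but it overlaps Ptpn7 on the opposite strand, so its reads are uncertain. Ptpn7, chosen after its values were seen, had a log2 change of 1.08 and lost its call in limma-voom (adjusted p = 0.0501), without any 1 control library or without Zac1 library 1 (edgeR adjusted p = 0.0549 to 0.109).

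**Figure D1:**
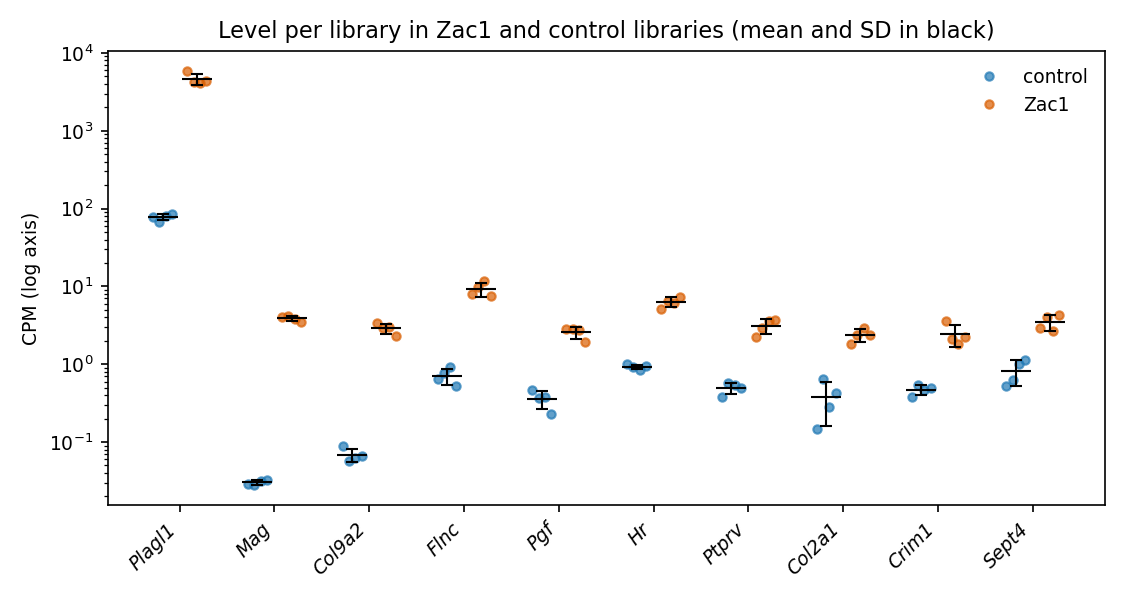
Level in CPM on a log axis of Plagl1 and 9 of the 10 genes with the largest increases under the naming rule, with 1 point per library (4 control, 4 Zac1) and black bars for the mean and SD. In each of the 10 genes every Zac1 library lies above every control library, which the naming rule required of the 9 genes other than Plagl1. Group means were 3.90 against 0.0305 CPM for Mag and 4631 against 77.8 CPM for Plagl1.

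Most of the increases were in genes with little expression in control cells. The control mean was below 1 CPM in 207 of the 308 higher genes (67.2%), against 12.5% of all tested genes, and below 0.1 CPM in 61. The filter removed genes near silence in both groups, so a gene near silence in the controls could be tested only if it was higher with Zac1. Part of this contrast with the tested genes is therefore built by the filter. The median control level of the higher genes was 0.459 CPM, against 22.4 CPM for all tested genes. In 7 of them no control library had a count. Only 28 had a control mean of at least 10 CPM, among them Nefh, the heavy neurofilament chain, which rose from 31.4 ± 0.60 to 69.5 ± 2.06 CPM (2.22-fold, edgeR adjusted p = 3.36e-09). The groups did not overlap in 311 of the 313 called genes, and in 830 (5.8%) of all tested genes, where chance gives 2.9%.

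Decreases were few without the replicate block. The 5 lower genes, named here after their values were seen, were 1700019B03Rik (log2 -1.67), 4931423N10Rik (-1.63), Tecta (-1.04), Atp8b3 (-1.03) and Slc17a8 (-0.90), each with a mean below 50 counts. Without control libraries 1, 2, 3 or 5 the fit called 3, 2, 1 and 3 lower genes, and without Zac1 libraries 1, 2 or 3 it called 2, 3 and 2. Without both libraries numbered 5, 1700019B03Rik, Atp8b3 and Slc17a8 lost their calls (edgeR adjusted p = 0.144, 0.135 and 0.0541). At an unadjusted p under 0.05 there were 810 higher and 277 lower genes. With the replicate number as a block, 628 genes were called, 512 higher and 116 lower, and all 313 calls were kept. On simulated, unpaired counts the blocked fit made 24 false calls among 198, against 15 among 191 without the block. The 116 blocked decreases had a median log2 of -0.18, and 107 of them were smaller than 1.5-fold. The share of blocked calls that were higher was 81.5% with TMM and 92.5% of 590 calls with library totals only.

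**Figure D2:**
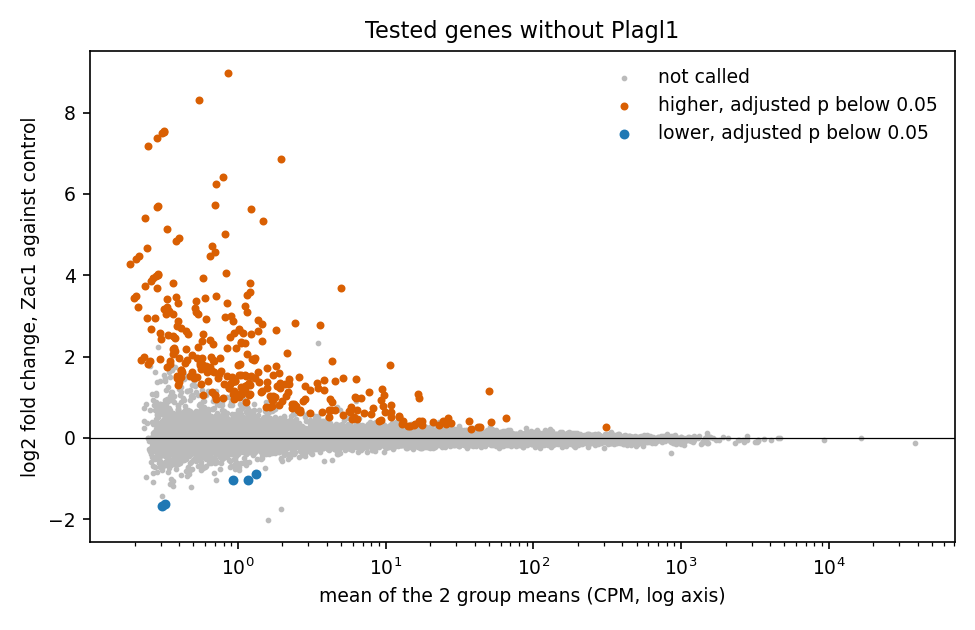
Log2 fold change of each tested gene other than Plagl1 (vertical axis) against the mean of both group means in CPM (horizontal log axis), with the higher genes in orange and the 5 lower genes in blue. Most of the higher genes lie at low levels, and fitted values of the 7 genes with 0 control counts, up to 8.97, depend on the prior count and are not estimates of a fold.

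The title of the series names the imprinted gene network, a set of imprinted genes reported to be expressed together with Plagl1. H19, a noncoding RNA, was the single called gene among 18 tested network members and among 62 tested imprinted genes. It had 0 counts in each control library and 1.72 ± 0.339 CPM in the Zac1 libraries, at least 75.5-fold higher against a floor of 3 counts over the control group (edgeR adjusted p = 5.16e-06). Its genomic neighbour Igf2 stood at 1483 ± 76.3 CPM in the Zac1 libraries and 1497 ± 44.1 CPM in the controls (log2 -0.01 ± 0.05). Peg3, at 1589 ± 46.0 against 1563 ± 128 CPM, had a log2 change of 0.02 ± 0.06. The noncoding RNAs Meg3 and Rian differed by log2 0.00 ± 0.05 and 0.01 ± 0.05, and Mirg by -0.04 ± 0.09. Gnas and the amino acid transporter Slc38a4 each gave -0.03 ± 0.05, Dlk1 -0.03 ± 0.09, and the receptor Igf2r 0.03 ± 0.05. Less precise values were found for Gatm (-0.06 ± 0.10), Ndn (-0.10 ± 0.12), Asb4 (-0.15 ± 0.15), Mest (0.14 ± 0.12), Grb10 (0.17 ± 0.20) and the cell cycle inhibitor Cdkn1c (0.18 ± 0.26). Dcn, Sgce and Peg10 had too few counts to be tested.

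As a share, 1.61% of imprinted genes were called against 2.18% of the 14268 other genes (odds ratio 0.74, 95% interval 0.02 to 4.29, Fisher's exact p = 1, also adjusted). For network members the share was 5.56% (odds ratio 2.65, 0.06 to 17.0, Fisher's exact p = 0.327, adjusted p = 0.809). Adjusted over the list alone, the calls numbered 2 of 62 and 1 of 18. The network had a median log2 change of -0.005 and a mean of 0.507, set apart by the fitted value of H19, and it did not pass camera (camera adjusted p = 0.357). The self-contained test fry, which does not compare the list with other genes, passed (fry adjusted p = 0.0492). The imprinted list had a median of -0.03, a mean of 0.159 and a downward camera direction (camera adjusted p = 0.845). With the block, 4 imprinted genes were called, 3 of them network members: H19, Ppp1r9a (log2 0.20, edgeR adjusted p = 0.00567), Nnat, which was lower (-0.15, edgeR adjusted p = 0.0219), and Begain (0.99, edgeR adjusted p = 0.0246). Without the block, Ppp1r9a and Nnat had edgeR adjusted p of 0.44 and 0.842, and Begain 0.0591. Without control library 5 Ppp1r9a was called as well (0.032), and without control library 3 or Zac1 library 5 Begain was (0.0315 and 0.0467), each of which brought the imprinted count to 2.

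**Figure D3:**
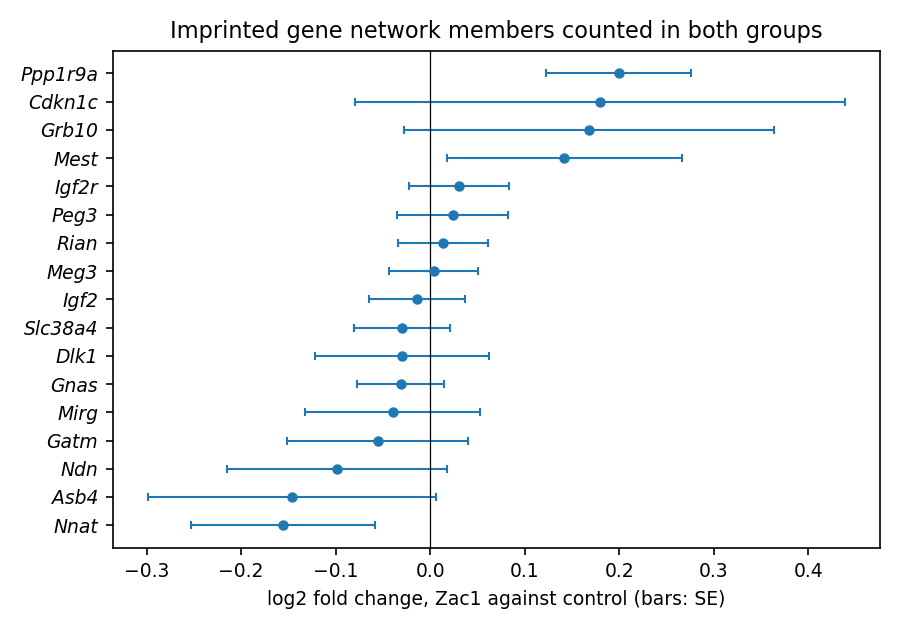
Log2 fold change (horizontal axis, Zac1 against control, bars are SE) of 17 tested imprinted gene network members, with H19 left out because it had 0 control counts. The values run from -0.16 for Nnat to 0.20 for Ppp1r9a.

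Genes reported elsewhere as regulated by Zac1 formed a list of 11 tested genes, of which 2 were called (H19 and Pparg) and 3 when adjusted over the list alone. Pparg, the nuclear receptor of adipocyte differentiation, rose 2.42-fold, from 1.08 ± 0.137 to 2.62 ± 0.459 CPM (edgeR adjusted p = 0.000619). The share called was 18.18%, against 2.16% of other genes (odds ratio 10.04, 1.05 to 48.78, Fisher's exact p = 0.0228), which did not pass after adjustment over the 47 lists (adjusted p = 0.0824), and the list was chosen from published work on Zac1 and is not independent. The camera adjusted p was 0.000248, and the adjusted p was 0.162 with an estimated correlation. The receptor Adcyap1r1 had a log2 change of 0.34 ± 0.25, Slc2a4 of 0.10 ± 0.20, Apaf1 of 0.09 ± 0.07 and Tcf4 of -0.06 ± 0.04, none past the threshold. Cdkn1a (0.15 ± 0.04) was the third gene past the threshold when adjusted over the list alone. With the block, Cdkn1a and Socs3 (0.27 ± 0.11) passed over all genes, at an edgeR adjusted p of 0.0264 and 0.0177.

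Genes of the extracellular matrix were the group named in the study's paper, so their lists are not independent evidence. Of 29 tested collagen chains 10 were called higher, 12 when adjusted over the list alone (camera adjusted p = 4.2e-12, and adjusted p = 0.0262 with an estimated correlation). Besides Col9a2 and Col2a1, these were the hemidesmosomal Col17a1, which rose 22.1-fold from 0.0514 ± 0.0488 to 1.25 ± 0.151 CPM, Col5a1 (13.9-fold), Col4a2 of basement membranes (8.63-fold), Col6a2 (7.37-fold), Col5a3 (5.93-fold), Col8a2 (3.89-fold), Col1a1 (3.08-fold) and Col7a1 (2.65-fold, 6.55 ± 1.02 against 2.47 ± 0.487 CPM). Only 29 of the 44 collagen chains were tested, and Col9a2, Col17a1, Col5a1, Col4a2 and Col6a2 passed the filter through the Zac1 libraries. The filter therefore raised the share called and the shift of this list. Among matrix glycoproteins 9 of 58 were called higher, 12 adjusted over the list alone (camera adjusted p = 3.17e-05, and adjusted p = 0.131 with an estimated correlation). The same limit holds for them, with 58 of 104 tested. Tnxb, a tenascin, rose 7.32-fold, the proteoglycan-like sulfated glycoprotein Papln 8.24-fold, Emilin2 of elastic fibres 9.13-fold, and Npnt, an integrin ligand, 1.87-fold. Mfap4, a microfibril protein, had between 1 and 3 counts in all control libraries together, and its ratio was 27.0 with a counting interval of 7.19 to 228. Matrix proteases and cross-linking enzymes had 5 of 49 members called (7 adjusted over the list alone; camera adjusted p = 0.0821), a share of 10.20% against 2.15% of other genes (odds ratio 5.17, 1.59 to 13.13, Fisher's exact p = 0.00413, adjusted p = 0.0277), of which Mmp15, a membrane-type protease, rose 3.05-fold. That count was 1 without control library 1, Zac1 library 2 or Zac1 library 3, 2 without control library 3, and 3 without control library 2 or Zac1 library 1. Proteoglycans gave 0 of 19 in edgeR, with 3 higher at an unadjusted p under 0.05, 1 in DESeq2 and 1 in limma-voom (camera adjusted p = 0.117), 2 when adjusted over the list alone and 2 with the block.

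Ligands and response genes of the Wnt pathway formed a second group, with 7 of 37 tested members called higher and 9 adjusted over the list alone (camera adjusted p = 7.41e-09, and adjusted p = 0.00928 with an estimated correlation). Notum, a secreted enzyme that inactivates Wnt proteins, rose 49.6-fold from 0.0462 ± 0.0385 to 2.42 ± 0.320 CPM. The ligands Wnt7b and Wnt2b rose 14.1-fold and 3.88-fold, and Wnt10a, with 1 to 3 control counts, had a ratio of 43 (counting interval 11.6 to 360). Only 37 of the 64 Wnt pathway genes were tested, and Notum, Wnt7b and Wnt10a passed the filter through the Zac1 libraries. The share called and the shift of this list were therefore raised by the filter. Axin2, a feedback target of the pathway, rose 1.51-fold at a higher level, from 6.38 ± 0.859 to 9.64 ± 1.19 CPM. Wnt10b (log2 1.52) lost its call without control library 2 or 3 or Zac1 library 1 or 2 (edgeR adjusted p = 0.0887, 0.0892, 0.0756 and 0.068), and the receptor Fzd6 (log2 0.29) lost it without any 1 library (edgeR adjusted p = 0.0563 to 0.156) and in limma-voom (adjusted p = 0.0561).

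Ligands and receptors of axon guidance were the other list that passed with an estimated correlation: 10 of 56 tested members were called higher, 15 adjusted over the list alone (camera adjusted p = 1.92e-07, and adjusted p = 0.00928 with an estimated correlation). The plexin Plxnc1 rose 5.06-fold and its ligand Sema7a 3.24-fold. Epha2, an ephrin receptor, rose 2.52-fold, Plxnd1 2.33-fold from 2.09 ± 0.230 to 4.88 ± 0.264 CPM, Sema3f 2.32-fold, Sema5b 1.71-fold, the netrin receptor Unc5b 1.54-fold and Plxna1 1.34-fold. Plxna4 (log2 1.51) lost its call without control library 2 (edgeR adjusted p = 0.0704) and without both libraries numbered 5 (0.0677). Plxna2 (log2 0.28) lost it without control library 2 or 3 or Zac1 library 1 or 2 (edgeR adjusted p = 0.0542, 0.0634, 0.063 and 0.052).

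**Figure D4:**
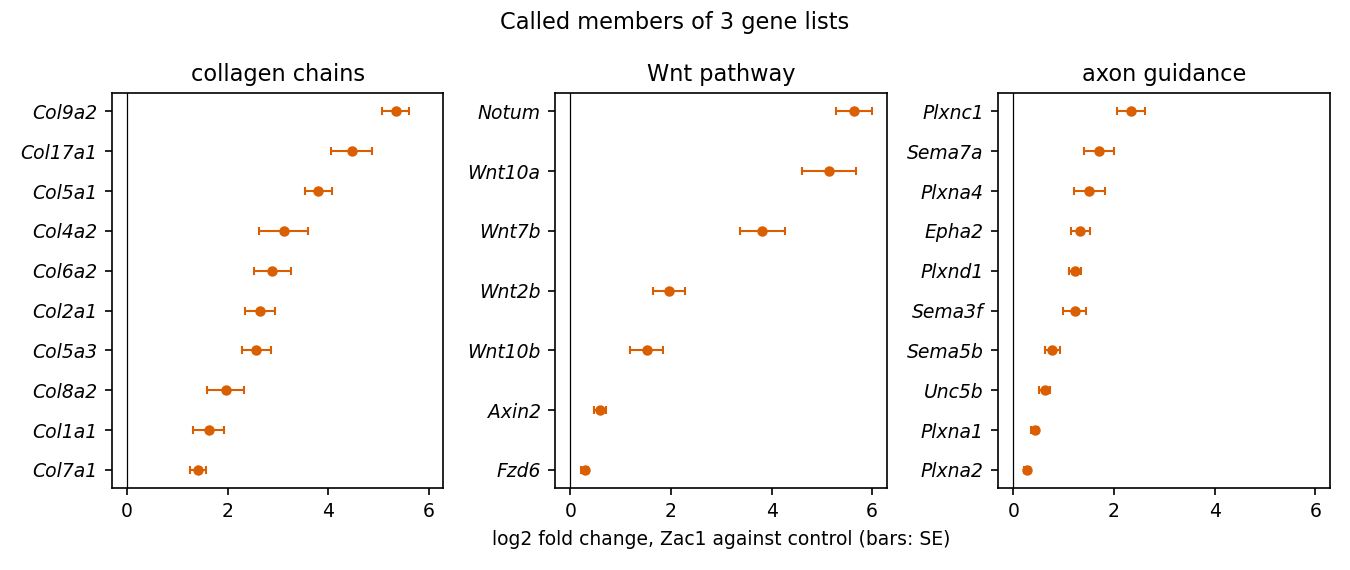
Log2 fold change (horizontal axis, Zac1 against control, bars are SE) of the called collagen chains (10), Wnt pathway members (7) and axon guidance members (10). The values run from 0.28 for Plxna2 to 5.63 for Notum, and all lie above 0. For members with few control counts, such as Notum and Col9a2, the bars are smaller than the counting error.

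Several other signalling and adhesion lists passed camera with the preset correlation but not with an estimated one. Integrins and focal adhesion components had 4 of 36 called higher, 5 adjusted over the list alone (camera adjusted p = 0.00583, and adjusted p = 0.25 with an estimated correlation). Besides Flnc, these were the fibronectin receptor chain Itga5 (15.8-fold), the adhesion adaptor Tns1 (9.44-fold) and Itgb7 (2.62-fold). Itga5 had 0 to 2 counts per control library, so its fold is imprecise. The Notch and Hedgehog list had 4 of 37, 7 adjusted over the list alone (camera adjusted p = 0.000866, and adjusted p = 0.222 with an estimated correlation). Smo, the Hedgehog signal transducer, had a ratio of 32.8 (counting interval 10.9 to 161) from 1 to 3 control counts, Notch4 rose 3.11-fold, and the Notch ligand Jag1 rose 2.26-fold from 2.35 ± 0.389 to 5.31 ± 0.339 CPM. Growth factors and their receptors had 4 of 38 called, and 4 adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.131 with an estimated correlation), among them Pdgfb (7.74-fold), Erbb2 (5.30-fold) and Fgfr3 (2.35-fold). The fold of Pdgfb is imprecise too, at 0 to 3 counts per control library. Among genes with a mean of at least 50 counts, these 3 lists and the matrix glycoproteins each had a camera adjusted p = 0.0737.

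Ion channels had 5 of 45 called, 6 adjusted over the list alone (camera adjusted p = 1.24e-05, and adjusted p = 0.187 with an estimated correlation), and the potassium channel Kcnn1 rose 1.77-fold. That count was 2 without control library 3 or Zac1 library 2, and 3 without Zac1 library 1 or 3. With the block it was 8. The list of cAMP signalling genes had 4 of 35, and 4 adjusted over the list alone (camera adjusted p = 0.000575, and adjusted p = 0.0526 with an estimated correlation), among them the phosphodiesterase Pde4a (1.62-fold) and the adenylate cyclase Adcy7 (1.55-fold). That count was 2 without control library 1 or Zac1 library 1. PPAR and adipogenic genes had 2 of 22, Pparg and Ppara (3.75-fold), and 2 adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.187 with an estimated correlation). The camera call of this list was lost without control library 1 or 5 or Zac1 library 1, 2 or 5 (camera adjusted p = 0.0621, 0.117, 0.0548, 0.0691 and 0.0874), and with library totals or upper-quartile factors (0.0559 and 0.0561), among genes with a mean of at least 50 counts (0.0737) and without both libraries numbered 5 (0.144).

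Genes of beta cell identity were compared as the background of the line. In edgeR 0 of 30 beta cell transcription factors and 0 of 60 beta cell function genes were called, adjusted over all genes or over the list alone. At an unadjusted p under 0.05, the first list had 2 higher and 0 lower, the second 1 higher and 1 lower, and DESeq2 and limma-voom called 0 in both. With the block 1 transcription factor was higher, and 1 function gene was higher and 2 lower. Ins2 stood at 37038 ± 3007 CPM in the Zac1 libraries and 40170 ± 6669 CPM in the controls (log2 -0.12 ± 0.11), and Ins1 had a log2 change of -0.04 ± 0.10. The function list had a median log2 change of -0.036 (camera adjusted p = 0.036, and adjusted p = 0.316 with an estimated correlation), a call lost without control library 1 or 2 or Zac1 library 3 or 5 (camera adjusted p = 0.235, 0.0994, 0.058 and 0.25) and with library totals or upper-quartile factors (0.0625 and 0.0563), and among genes with a mean of at least 50 counts (0.0685). The transcription factors had a median of -0.002 (camera adjusted p = 0.906). Of 18 genes usually kept low in beta cells 2 were called, and 3 adjusted over the list alone (camera adjusted p = 0.219), among them Fcgrt, the neonatal Fc receptor (15.2-fold). That count was 1 without control library 2 or Zac1 library 2 or 3, and with the block 3 were higher and 1 lower.

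Markers of other cell types were tested as separate lists. In edgeR 0 of 14 markers of other islet hormone cells, 0 of 15 of duct cells, 0 of 4 of acinar cells and 0 of 7 of immune cells were called, by DESeq2 and limma-voom also 0, and at an unadjusted p under 0.05 these lists had 2, 1, 0 and 1 genes. The camera adjusted p was 0.726 for other islet cells, 0.517 for duct cells and 0.582 for immune cells. With the block 1 duct marker was called. Fibroblast and stellate markers had 2 of 9 called, Des and Col1a1 (camera adjusted p = 0.372, fry adjusted p = 0.00682), a share of 22.22% against 2.16% of other genes (odds ratio 12.90, 1.30 to 68.19, Fisher's exact p = 0.0154, adjusted p = 0.0603), and endothelial markers 1 of 7, the VEGF receptor Flt1 at 9.38-fold (camera adjusted p = 0.343). Contractile and muscle genes had 4 of 23 called and 7 adjusted over the list alone, 6 higher and 1 lower, and with the block 6 higher and 1 lower (camera adjusted p = 0.0557, and 0.0307 with the block; fry adjusted p = 0.000598). Their share called, 17.39%, exceeded the 2.15% of other genes (odds ratio 9.56, 2.35 to 28.99, Fisher's exact p = 0.00141, adjusted p = 0.0133). Only 23 of the 50 contractile and muscle genes were tested, and Des and Ckm, at control means of 0.043 and 0.044 CPM, passed the filter through the Zac1 libraries. The filter therefore raised this share, and the same limit holds for the fibroblast list, with 9 of 25 tested. Desmin (Des) rose 32.5-fold from 0.0431 ± 0.0546 to 1.58 ± 0.372 CPM, the muscle creatine kinase Ckm 26.4-fold and the calponin Cnn1 4.51-fold. Counts per control library were at most 4 for Des, 3 for Ckm and 2 for Flt1, so the folds of these genes are imprecise. Neuronal genes had 3 of 45 called, and 3 adjusted over the list alone, with Nefh and the adhesion molecule Cntn2 (2.64-fold) among them, while the list had a median log2 change of -0.023, a mean of 0.06 and a downward camera direction (camera adjusted p = 0.939). Transcription factors and markers of epithelial to mesenchymal transition gave 0 of 20 in edgeR, DESeq2 and limma-voom, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.679).

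Housekeeping and cell cycle lists showed shifts below 0.1 in median log2 with few single calls. Ribosomal protein genes had a median of -0.082 (camera adjusted p = 1.08e-06, and adjusted p = 0.368 with an estimated correlation), with 0 of 64 called in edgeR, DESeq2 and limma-voom, 5 lower at an unadjusted p under 0.05, and 9 lower with the block. G2 and mitosis genes had a median of -0.06 (camera adjusted p = 3.07e-05, and adjusted p = 0.481 with an estimated correlation), 0 of 51 called in the same tools, 5 lower at an unadjusted p under 0.05 and 3 lower with the block. That camera call was lost without control library 5 (camera adjusted p = 0.124). Respiratory chain genes had a median of -0.04 (camera adjusted p = 0.00417, and adjusted p = 0.363 with an estimated correlation), with 0 of 45 called, 2 lower at an unadjusted p under 0.05 and 5 lower with the block, a call lost without control library 3 or Zac1 library 2 (camera adjusted p = 0.0688 and 0.108). Cytosolic chaperones had a median of -0.069 and a mean of -0.303 (camera adjusted p = 6.65e-05, and adjusted p = 0.187 with an estimated correlation), with 0 of 19 called and 3 lower at an unadjusted p under 0.05. The near-identical Hspa1a and Hspa1b, chosen after their values were seen and whose reads cannot be split with certainty, stood at 2.58 ± 3.18 and 3.03 ± 3.40 CPM in the controls and 0.639 ± 0.258 and 0.908 ± 0.278 CPM in the Zac1 libraries. With the block 0 chaperones were called, but with the block and thinned counts Hspa1b was (log2 -1.62, edgeR adjusted p = 0.0049), while Hspa1a was not (0.0618). Without control library 1 their log2 changes were -0.54 and -0.62.

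Stress and growth response lists held single or no calls. Immediate early genes had 1 of 28 called, Klf10 at 1.24-fold (2 adjusted over the list alone; camera adjusted p = 0.000464, and adjusted p = 0.222 with an estimated correlation), and Klf10 lost its call without control library 1 or 2 or any Zac1 library (edgeR adjusted p = 0.0587 to 0.133). The cytokine Lif (1.94-fold) was the 1 call among 24 growth factor feedback genes (camera adjusted p = 0.0801) and among 21 NF-kB response genes (camera adjusted p = 0.00417, and adjusted p = 0.222 with an estimated correlation), and it lost its call without any 1 library (edgeR adjusted p = 0.063 to 0.166), in DESeq2 (adjusted p = 0.0834) and in limma-voom (adjusted p = 0.0522). The NF-kB list lost its camera call without control library 5 (0.0568). Osgin1 (2.06-fold) was called among 22 NRF2 targets (camera adjusted p = 0.679) and Gadd45b (1.54-fold) among 14 CDK inhibitors and related genes (camera adjusted p = 0.365). Osgin1 lost its call without control library 1, 2 or 5 or Zac1 library 2 or 3 (edgeR adjusted p = 0.0655 to 0.119), and Gadd45b without any 1 library other than Zac1 library 5 (edgeR adjusted p = 0.088 to 0.178) and in limma-voom (adjusted p = 0.0922). With the block the calls numbered 3 for immediate early genes, 3 for NF-kB response genes, 2 for growth factor feedback genes, 1 higher and 1 lower for NRF2 targets, and 2 higher and 1 lower for CDK inhibitors. Without control library 3 the immediate early genes had 2 calls. The insulin and IGF pathway had 1 of 34 called, the RNA-binding Igf2bp2 at 2.24-fold, and 2 with the block (camera adjusted p = 0.337). In edgeR p53 targets gave 0 of 39 with 5 higher at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom and 5 higher with the block (camera adjusted p = 0.00852, and adjusted p = 0.194 with an estimated correlation), and the camera call was lost without control library 1 or Zac1 library 5 (0.0525 and 0.058). S phase genes gave 0 of 50, none at an unadjusted p under 0.05 nor in DESeq2 or limma-voom (median log2 0.035, camera adjusted p = 0.0175, and adjusted p = 0.235 with an estimated correlation), a call lost without control library 1 or Zac1 library 5 (0.0948 and 0.0733).

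Chaperones and sensors of the unfolded protein response gave 0 of 33 by each tool and at an unadjusted p under 0.05 (camera adjusted p = 0.0477, and adjusted p = 0.625 with an estimated correlation), and the camera call was lost without control library 1 or Zac1 library 2, 3 or 5 (0.891, 0.108, 0.127 and 0.242) and with RLE, library totals or upper-quartile factors (0.0509, 0.0945 and 0.0902), among genes with a mean of at least 50 counts (0.0746) and without both libraries numbered 5 (0.0508). Lysosome and autophagy genes gave 0 of 36 by each tool, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0175, and adjusted p = 0.235 with an estimated correlation), lost without control library 1 or Zac1 library 1 or 2 (0.0827, 0.0888 and 0.0691). TGF-beta and BMP genes gave 0 of 38 in edgeR, with 5 higher at an unadjusted p under 0.05, 3 in DESeq2, 0 in limma-voom, 3 adjusted over the list alone and 4 with the block (camera adjusted p = 0.185). ATF4 and CHOP targets gave 0 of 38, with 3 at an unadjusted p under 0.05 and 1 in DESeq2 (camera adjusted p = 0.139), and interferon-stimulated genes 0 of 35, with 1 at an unadjusted p under 0.05 and 1 in DESeq2 (camera adjusted p = 0.3). Apoptosis genes gave 0 of 39 by each tool, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.939), sterol and fatty acid synthesis 0 of 34 with 1 (camera adjusted p = 0.0616, and 0.0225 with the block), and histones 0 of 12 with 2 (camera adjusted p = 0.392). With the block 1 gene was called in each of the lists of ATF4 and CHOP targets, interferon-stimulated, apoptosis, lysosome and unfolded protein response genes, the last of them lower.

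Glycolysis and hypoxia response genes had 1 of 35 called, the carbonic anhydrase Car9 at 5.74-fold (edgeR adjusted p = 0.00832), with a median log2 change of -0.039, a mean of 0.062 and an upward camera direction (camera adjusted p = 0.845). With the block 2 members were higher and 1 lower, the hexokinase Hk1 (log2 -0.17, edgeR adjusted p = 0.0165, and 0.374 without the block). This list varied with the replicate number in both groups. Its median log2 deviation from the other libraries of the group was 0.74 in control library 1 and 0.52 in Zac1 library 1, -0.67 in both libraries numbered 5, and between -0.07 and 0.07 in the libraries numbered 2 and 3. For G2 and mitosis genes the deviation was 0.19 in both libraries numbered 5.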

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

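The tests of the libraries numbered 5 by hypoxia genes and by depth, the test by expression level and the test of head to head pairs were chosen after the results they bear on were seen, as were the alternatives with thinned counts and the GC correction. Among 234 groups of 4 libraries examined for a library far from the other 3, 16 stood out, and chance alone gives about 1 in 20.

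The total count of Zac1 library 2, 34.7 M, lay below the 41.2 to 42.4 M of the other Zac1 libraries. In Zac1 library 1 Plagl1 took 0.582% of counts, against 0.415% to 0.435% in the others. Control library 1 had the highest Hspa1a and Hspa1b levels, 7.34 and 8.13 CPM, against 0.938 to 1.05 and 1.25 to 1.41 CPM in the other controls. Zac1 library 5 was the lowest of its group for Col1a1 (0.544 CPM), Pgf (1.92), Mirg (15.2) and Ndn (4.42), where the other Zac1 libraries started at 1.12, 2.72, 17.6 and 5.83 CPM. Control library 5 was the highest of its group for Epha2 (1.60 CPM) and Fgfr3 (1.37 CPM), above 1.08 and 1.11 CPM, and the lowest for Smo, with 0 CPM. Zac1 library 3 was the lowest for Meg3 (576 CPM, others from 622) and Igf2bp2 (1.11 CPM, others from 1.62), and Zac1 library 1 the lowest for Fzd6 (14.6 CPM, others from 15.8). For the paralogs, control library 3 had the lowest Plag1 level (0.565 CPM, others from 1.11) and control library 2 the highest Plagl2 level (22.1 CPM, others up to 20.4).

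The called genes were mostly higher with Zac1, 308 against 5. This share stayed at 98.9% with counts thinned to 1 depth, at 98.4% or more under 3 other scalings, and at 98.6% with the GC correction, which argues against depth, scaling or a GC trend as its whole cause in the fit without the block. With the block the share was 81.5%, 82.6% after thinning, 85.3% with the GC correction and 92.5% with library totals. Whether decreases were hidden because many genes lay near silence cannot be told apart from a true excess of increases, since the fits differ: among called genes at 10 CPM or more the lower 95% limit of the percent higher was 89.1 without the block (32 higher and 0 lower) and 51.4 with it (140 higher and 102 lower). Activation by Zac1, the factor the groups differ in, and a time after transfection of 16 h too short for stable transcripts to fall may both contribute and were not tested.

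The libraries numbered 5 stood apart in both groups, and the first principal component (38.5% of variance) placed them at 9.44 and 18.22, above the other libraries. The tables argue against depth as the cause, since control library 5 was the shallowest and Zac1 library 5 the deepest of its group (a product of sides of -1). A GC trend is also argued against, since the shift of the glycolysis and hypoxia list kept 101% of its size after the GC correction. A lower hypoxia response in both of these cultures may contribute and stays open: the 17 hypoxia genes of the list that are not glycolytic enzymes shifted by a median log2 of -0.68 in control library 5 and -0.74 in Zac1 library 5, but they belong to the list in which the shift was seen, so this is no separate test. Oxygen, cell density and passage are not given in the sources used here, and what made these cultures differ was not tested.

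In the order of the 13656 tested genes with a known place, which skips untested genes, called genes were adjacent more often than matched random sets. They formed 16 adjacent pairs against a median of 7 (permutation p = 0.0039 over 10000 sets matched on mean expression). That argues against chance order among genes of like mean expression, since the central 95% range of the random sets ended at 13. The sets were not matched on GC content or length. The higher genes had a median GC content of 56.5%, against 51.3% for random sets matched on mean expression. An uneven order of genes by GC content or length was therefore not excluded. Reads running on from 1 gene into the next may contribute and stay open: 31.2% of the 16 pairs lay on the same strand, against 47.6% of all adjacent pairs (one-sided exact binomial p = 0.943), but this speaks against run-on only where the counting used strand, which is not given in the sources used here. Head to head pairs, which reads cannot run between, numbered 4 against a random median of 1 (permutation p = 0.0557), and the other pairs 12 against 6 (permutation p = 0.0173), so neither test excludes it. Shared regulation of neighbours was not tested, and the pairs, chosen after their values were seen, included Duox1 and Duox2, Wnt7b and Ppara, and the overlapping Ptprv and Ptpn7.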

How the results depend on the processing

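The alternatives with both libraries numbered 5 left out, thinned counts or the GC correction were chosen after seeing the data. No result reversed, and the cause was not tested where none is named. The 313 calls became 99 with a mean of at least 50 counts (99 higher, 0 lower), where 189 of the 313 lay below that level, 628 with the replicate block (512 higher, 116 lower), 648 with the block and GC correction (553 and 95) and 517 with the block and thinned counts (427 and 90). Lower genes numbered 8 with DESeq2, 2 with a test against 1.2-fold and 3 with thinned counts. Imprinted genes called numbered 2 with library totals, 3 with no filter, 0 at a mean of 50 counts, 4 with the block, 2 without the libraries numbered 5, 2 with the GC correction, 5 with the block and GC correction and 3 with the block and thinned counts. Network members numbered 0, 3, 2, 3 and 3 at a mean of 50 counts, with the block, without the libraries numbered 5, and with the block plus GC correction or thinning. Of 47 lists, 22 were called with camera's preset correlation (15 upward, 7 downward), 3 with an estimated correlation and 13 with fry.

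Leaving out each library gave 262 to 362 calls, 260 to 357 higher and 1 to 5 lower, 1 to 2 imprinted genes, 1 to 2 network members, 17 to 24 lists and a log2 of 5.77 to 5.95 for Plagl1. Of the 313 genes, 242 to 298 stayed called in these fits, 305 with DESeq2 (349 calls), 292 with limma-voom (296), 279 without the libraries numbered 5 (331) and 309 with the GC correction (361). RLE gave 316, library totals 339, upper quartile 327, no filter 426, the 1.2-fold test 236, thinned counts 275 and Plagl1 left out of scaling 313. Over the genes reported in the text, which are only part of those that the rule names, 111 results fell behind the threshold, 24 newly passed it and 2401 did not change side. The block changed no call of a named gene or list beyond those given beside the results. Of the list results, 71 lost and 281 kept their call. DESeq2 gave no adjusted p for 2 genes. Depth limits genes with 0 control counts to lower bounds.

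Of 35 splits of the libraries into 4 and 4, the real 1 gave 313 genes and the highest other 0. These splits take the libraries as unpaired, so they do not exclude chance under the pairing by replicate number. The 8 splits that part all pairs (highest other 0) are too few for a share under 0.05. For imprinted genes the real value was 1 and the highest other 0, which decides nothing, since the other splits called no gene at all. For lists, 1 of the 35 reached the real 22, but another split, which set control libraries 1, 3 and 5 with Zac1 library 5 against the rest, gave 21, and 1 parting all pairs gave 19, so other structure of the samples moves nearly as many lists. With an estimated correlation the real split called 3 lists and the others 0.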

Other observations

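The comparison of GC content was chosen after the calls were seen. The genes that rose had GC-rich transcripts. The median GC content of the 304 higher genes with an annotated value was 56.5%, against 49.7% for all tested genes and 51.3% for random sets matched on mean expression. None of 10000 such sets reached it, and their central 95% range ended at 52.3%. The median length was 4240 bases against 3460 for tested genes. With the correction for GC trends between libraries, 309 of the 313 calls remained.

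Of 35 tested glycolysis and hypoxia genes, 31 were lower in both libraries numbered 5 than the mean of the other libraries of each group, 3 were higher in both and 1 differed in sign. The 3 were Hk1 (log2 0.17 in control library 5 and 0.05 in Zac1 library 5), Hif1a (0.10 and 0.18) and Car9 (0.11 and 1.09), the list's called gene. Among the lower genes, 3 were chosen after their values were seen, of which the lactate transporter Slc16a3 had a log2 of -2.44 in control library 5 and -2.06 in Zac1 library 5. The mitophagy gene Bnip3 had -1.60 and -1.50, and the lactate dehydrogenase Ldha -1.54 and -1.46. The share of counts taken by Ins1 and Ins2 was lowest of the controls in library 5, at 3.82%. In the Zac1 group it was lowest in library 2, at 4.33%, with library 5 at 4.37%.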
